A study of Mus musculus with 6 samples.

How the data were processed

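Poly(A)-selected RNA of 6 mouse leukemia samples was sequenced as 100-base single-end reads, per the labels' protocols. The deposited table gave raw read counts per gene for the 6 libraries, 1 column each, with 23337 genes. Counting used featureCounts 1.5.1 restricted to primary alignments, with the UCSC mm10 gene annotation, per the file headers. Trimmomatic, Bowtie, TopHat and DESeq2 are named without versions per the submitters' processing notes, and how each was applied is not given in the sources used here. The counting command set no strand option, so reads of overlapping or antisense genes cannot be told apart. It counted a read with several alignments at its primary one, which can move reads between near-identical copies such as ferritin, stefin, lysozyme and ribosomal protein genes and their pseudogenes. Coordinates are those of the file (mm10, counted from 1, from the lowest exon start to the highest exon end), and gene symbols are those of the file, some of them older names.

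Groups came from the treatment labels and the titles, 3 libraries per group. Replicate numbers were not shared between the groups as a pairing, so the model held no block. Counts were scaled by TMM and low genes were removed with filterByExpr (default minimum count 10), which left 12174 of the 18580 genes with at least 1 count. Differences were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are ccl5 over control on the log2 scale. Their SE is the absolute log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes and are given as mean ± SD of 3 libraries or per library.

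There were 29 gene lists with 763 symbols, fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Of the symbols 23 were not in the file and 11 were matched by an older name. The 25 lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, Benjamini-Hochberg adjusted over these lists. Alternatives were camera with the correlation estimated per list and fry, which tests whether a list's genes move on balance 1 way. The list of sex-linked genes was given per library and not tested. The rule named up to 10 genes per direction with the largest fold change past the threshold and no overlap between groups. Since fewer than 5 passed, it took the 5 genes with the smallest p in each direction at an average log2 CPM of at least 1, passing over predicted genes. It also took up to 3 members with the smallest p from each called list and each lineage list, 1 from every other list, and a fixed set of CCL5 receptor, lineage and leukemia genes. A few genes that the rule names are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

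The test was tried on simulated counts drawn from the means, library sizes and dispersions of the real genes, for ccl5 against control, with 200 of 12029 tested genes changed by known folds. Of the changed genes, 0 of 50 were recovered at 2-fold, 17 of 50 at 4-fold, 29 of 50 at 8-fold and 43 of 50 at 16-fold, with 0 unchanged genes called. A 2-fold change in a single gene was thus out of reach at the spread between these libraries. With no gene changed 0 genes and 0 lists were called, and a list raised 2-fold was the only list called. The genes were drawn independently of each other, while the estimated correlation within the real G2/M list was 0.984. The simulation therefore cannot tell how often lists are called without an effect in these data.

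Alternatives fixed in advance were DESeq2 size factors (DESeq2 1.42.0), no filter and a stricter filter (CPM over 1 in at least 3 libraries), thinning to the smallest library, 1 surrogate variable (sva 3.50.0), leaving out receptor segments and haemoglobin, leaving out each library in turn, primary transplant libraries only, DESeq2's Wald test, limma-voom with quality weights, a test against a 1.5-fold change, and a threshold of 0.1. An analysis of only the libraries with Y-linked reads was added after the data were seen. Similarity between libraries was the Pearson correlation of log2 CPM with a prior count of 2. Between single libraries, list medians of the log2 ratio were set against 10000 random lists of the same size, matched on mean expression. The column of gene lengths was not used.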

Results

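Expression was measured by sequencing polyadenylated RNA from mouse leukemia described as neonatal, either treated with CCL5 or kept under control conditions. CCL5 is a chemokine, and Ccr1 and Ccr3 encode receptors for it. There were 6 libraries, 3 labelled ccl5 and 3 labelled control. The labels place ccl5 replicates 2 and 3 and control replicate 3 in a primary transplant and ccl5 replicate 1 in a tertiary transplant, and they give no transplant for control replicates 1 and 2. Gene counts summed to 16613837, 13840229 and 13421100 in ccl5 replicates 1 to 3 and to 15516356, 18445095 and 15507823 in control replicates 1 to 3. At these depths 3 counts in a library correspond to between 0.16 and 0.273 CPM (counts scaled to library size), and values at or below that level are not told apart from 0. The labels do not say that the libraries came from separate animals or cultures, so p-values of single genes measure only the spread between these libraries. Camera p-values for lists set the list's genes against the other tested genes. At the preset correlation of 0.01 they do not measure how well a shift repeats across libraries.

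The comparison of ccl5 with control libraries asks how exposure to CCL5 alters gene expression in this leukemia, which carries an MLL rearrangement according to the series title. No gene passed the test against the spread between libraries, and the genes given here are examples whose groups did not overlap. C5ar1, the complement C5a receptor (chromosome 7, 16246743 to 16259540, mm10), measured 35.9 ± 8.74 CPM with CCL5 and 15.3 ± 4.49 CPM in controls (SD, n = 3 each). Its log2 fold change was 1.23 (SE 0.30). Cmklr1, the chemerin receptor (chromosome 5, 113612355 to 113650390), measured 7.20 ± 5.42 against 0.332 ± 0.212 CPM, with only 2 counts in control replicate 1. Lower levels with CCL5 were measured for Pgm3, an enzyme of hexosamine synthesis (chromosome 9, 86552476 to 86571842), at 18.5 ± 2.27 against 31.8 ± 4.49 CPM, and for Hoxa9, a homeobox gene that MLL fusions activate (chromosome 6, 52224054 to 52227370), at 91.3 ± 9.78 against 159 ± 44.8 CPM. For each of these genes the groups lay closest between ccl5 replicate 2 and control replicate 3. There C5ar1 measured 26.4 and 20.5 CPM, Cmklr1 0.977 and 0.550, Pgm3 21.1 and 26.6, and Hoxa9 101 and 108.

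Of 12174 genes tested with edgeR's quasi-likelihood test, 0 passed an adjusted p of 0.05 in either direction, and the smallest adjusted p was 0.365. At an unadjusted p under 0.05 there were 1663 genes, 1095 higher and 568 lower with CCL5, where independent libraries without an effect would give about 609. The 9 other splits of these libraries gave 0 to 2983, so the excess is not specific to the treatment. DESeq2 called 199 genes (118 higher, 81 lower) and limma-voom with sample quality weights called 8097 (4015 higher, 4082 lower). In 1919 genes (15.8%) the 3 ccl5 and the 3 control libraries did not overlap, where chance gives 10% for independent libraries. Of the 199 genes that DESeq2 called, edgeR tested 169, and the groups did not overlap in 82 of these. The count of 0 rested on single libraries: without ccl5 replicate 2 edgeR called 3299 genes, and without control replicate 3 it called 237. The first fit left ccl5 replicates 1 and 3, which were closely alike (Pearson r 0.993) and were the only libraries without Y-linked reads. Its calls therefore cannot be told apart from whatever else set these libraries apart. The second fit left control replicates 1 and 2, which were also closely alike (r 0.995). With all 6 libraries the fitted spread between libraries of a group corresponded to a coefficient of variation of 46.1%, and the median SE of a log2 fold change was 0.31.

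Because no gene passed, the genes with the smallest p in each direction are given as values. Besides Cmklr1 and C5ar1, those higher with CCL5 were Ncoa1, a nuclear receptor coactivator (56.9 against 28.4 CPM), Whsc2, a subunit of the negative elongation factor (log2 fold change 0.76, SE 0.18), and AI464131 (3.04, SE 0.75). Those lower, besides Pgm3, were Ccdc154 (-1.32, SE 0.32), Cdr2l (-3.37, SE 0.77), Crtac1 and Upp1, which encodes uridine phosphorylase. Upp1 had 1, 3 and 1 counts in ccl5 replicates 1 to 3, all at or below the floor of 3, so no fold is given. It measured 45.5, 41.6 and 0.715 CPM in control replicates 1 to 3, so control replicate 3 lay close to the ccl5 libraries. Crtac1 had the same layout, with 22.5 and 19.8 CPM in control replicates 1 and 2 and 0.880 CPM in control replicate 3, against 3, 5 and 1 counts in ccl5 replicates 1 to 3. Cdr2l was laid out likewise, at 7.48, 6.66 and 1.32 CPM in control replicates 1 to 3. It had 8, 10 and 3 counts in ccl5 replicates 1 to 3, the last at the floor, so its fold is uncertain. AI464131 measured 6.34, 1.16 and 5.64 CPM in the ccl5 libraries and 0.317, 0.480 and 0.770 CPM in the controls. Its difference thus lay mainly in ccl5 replicates 1 and 3. The adjusted p of each of these 10 genes was 0.365 in edgeR's quasi-likelihood test.

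**Figure D1:**
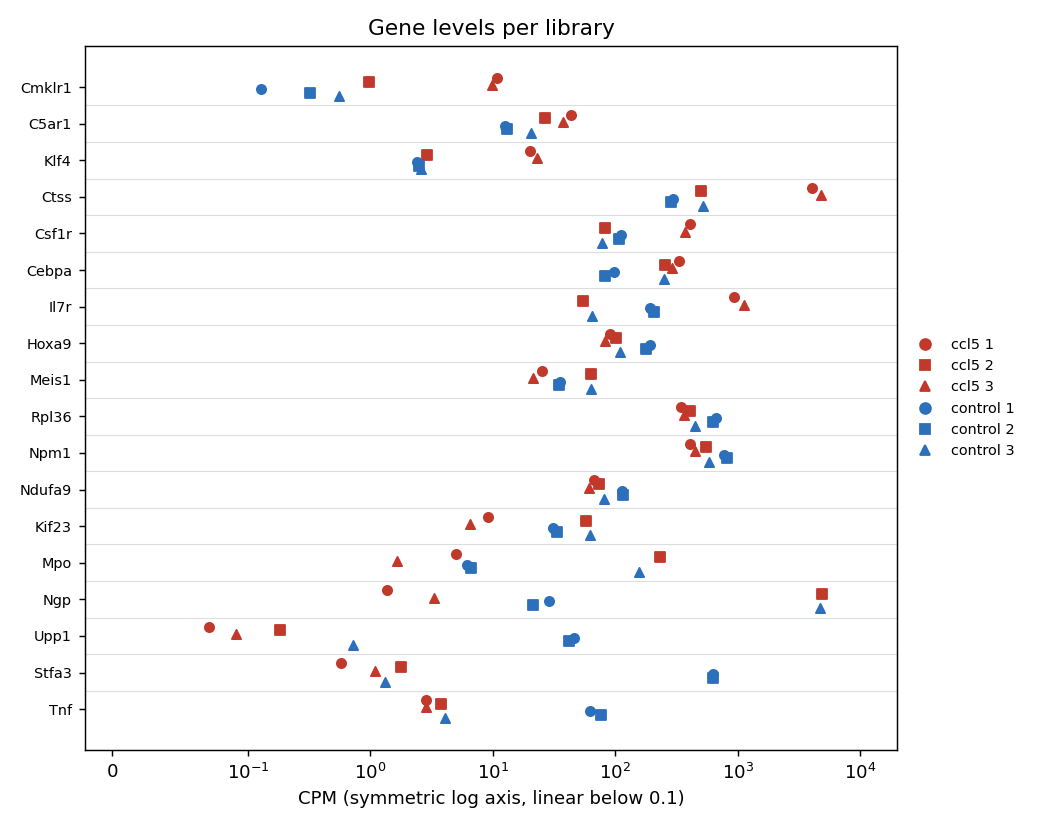
CPM of 18 genes on a symmetric log axis, with 1 point per library, coloured by group and shaped by replicate. For Mpo, ccl5 replicate 2 and control replicate 3 lie together at 232 and 156 CPM, while ccl5 replicates 1 and 3 measured 4.99 and 1.64 CPM.

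Ccr1 did not pass the test. It measured 132 ± 50.7 CPM with CCL5 and 196 ± 99.0 CPM in controls (log2 fold change -0.57, SE 0.52, adjusted p = 0.633 in edgeR). Ccr3 was below the filter, with 0, 1 and 0 counts in ccl5 replicates 1 to 3 and 0, 1 and 1 in control replicates 1 to 3. Ccl5 itself was also below the filter, with 4, 3 and 3 counts in the ccl5 libraries and 0, 0 and 9 in the control libraries. Of the 18 tested members of the list of CCL5 receptors and the chemokine system, 6 had a higher and 12 a lower fold change, and the list did not shift (camera adjusted p = 0.211). Ccl2, the monocyte chemoattractant, was its member with the smallest p, at 8.05, 12.3 and 6.64 CPM in the ccl5 libraries and 64.1, 80.6 and 11.7 CPM in the control libraries.

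Monocyte and macrophage genes rose as a group with CCL5 by camera with a preset correlation of 0.01 (adjusted p = 0.0132), with 23 of 32 members at a higher fold change and a mean log2 fold change of 1.01. With an estimated correlation the adjusted p was 0.71. Klf4, a transcription factor of monocytes, measured 15.2 ± 10.8 CPM with CCL5 and 2.41, 2.51 and 2.59 CPM in control replicates 1 to 3 (log2 fold change 2.60, SE 0.75), with ccl5 replicate 2 at 2.87 CPM. Ctss, which encodes the lysosomal protease cathepsin S, measured 4024, 499 and 4800 CPM against 296, 282 and 523 CPM (3.08, SE 0.85). For both genes the difference lay in ccl5 replicates 1 and 3. Among the 4 libraries with Y-linked reads, which leave both of these out, the list had a mean log2 fold change of -0.30. The mean log2 CPM of the list was 6.98, 5.64 and 7.03 in the ccl5 libraries and 5.49, 5.55 and 5.79 in the controls. The call was lost without ccl5 replicate 3 (mean log2 fold change 0.85, adjusted p = 0.0588) and without control replicate 3 (1.49, adjusted p = 0.0997).

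Genes of cell division and ribosome production fell as groups with CCL5 by the same test. All 31 G2/M and mitosis genes had a lower fold change (mean log2 -0.64, adjusted p = 3.44e-05), as did all 30 MYC and ribosome biogenesis genes (-0.53, adjusted p = 2.47e-06). Of 73 ribosomal protein genes 71 had a lower fold change (-0.47, camera adjusted p = 1.41e-17). Of them 68 had no overlap between the groups in either direction, against 15.8% of all tested genes. Ribosomal protein genes moved together (estimated correlation 0.746), so these members are not independent of each other. The direction turned for 2 of these 3 lists among the 4 libraries with Y-linked reads (1 ccl5 against 3 control), at 0.64 for the G2/M list and 0.08 for the MYC list. With an estimated correlation the adjusted p was 0.871 for the G2/M list, 0.71 for the MYC list and 0.71 for the ribosomal proteins. Kif23, a mitotic kinesin, measured 9.19, 57.3 and 6.55 CPM in ccl5 replicates 1 to 3 and 30.7, 33.4 and 61.6 CPM in control replicates 1 to 3. Anln, the contractile ring protein anillin, had the same layout, with 18.7, 117 and 12.8 against 69.0, 69.0 and 120 CPM, and Bub3, a mitotic checkpoint gene, had a log2 fold change of -0.49 (SE 0.32). Npm1, which encodes nucleophosmin, measured 466 ± 74.0 against 719 ± 123 CPM and Wdr43 measured 50.1 ± 15.4 against 77.2 ± 8.35 CPM. In ccl5 replicate 2 and control replicate 3, Npm1 measured 549 and 580 CPM and Wdr43 67.9 and 68.1. Odc1, the polyamine synthesis enzyme and a MYC target, measured 190 ± 3.97 against 594 ± 356 CPM, with control replicate 3 at 184 CPM. Rpl36 (log2 fold change -0.65, SE 0.21), Rpl32 (-0.75, SE 0.25) and Rpl27 (-0.64, SE 0.21) were lower in every ccl5 library than in every control library.

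Oxidative phosphorylation genes fell as a group by a small margin (28 of 38 members lower, mean log2 fold change -0.14, camera adjusted p = 0.0491), as did cholesterol synthesis genes (19 of 23 lower, -0.32, adjusted p = 0.0228). With an estimated correlation the adjusted p was 0.71 for both lists. Ndufa9, a subunit of respiratory complex I, measured 67.0 ± 6.77 CPM with CCL5 and 103 ± 19.4 CPM in controls. Uqcrq of complex III measured 126 ± 10.4 against 181 ± 35.7 CPM, and Cycs, which encodes cytochrome c, measured 217 ± 31.9 against 307 ± 42.7 CPM. Among cholesterol synthesis genes, Idi1 had a log2 fold change of -0.84 (SE 0.40), Cyp51 of -0.57 (SE 0.24) and Sc4mol, an older symbol of Msmo1, of -0.41 (SE 0.19). The oxidative phosphorylation call was kept only without ccl5 replicate 3 among the 6 fits that left out a library, with adjusted p from 0.0659 to 0.15 in the other fits. The cholesterol call was lost without ccl5 replicate 1 (mean log2 fold change -0.16, camera adjusted p = 0.0742) and without ccl5 replicate 3 (-0.12, camera adjusted p = 0.136). It was also lost without control replicate 3 (-0.27, camera adjusted p = 0.179), where the shift stayed near its size with all libraries. The sign of the cholesterol shift turned among the libraries with Y-linked reads (0.14).

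The sizes of the G2/M, MYC and cholesterol shifts depended on single libraries. Without ccl5 replicate 2 the mean log2 fold change was -2.68 for the G2/M list, -1.11 for the MYC list and -0.65 for the cholesterol list. Without ccl5 replicate 1 it was -0.21 for the G2/M list and -0.16 for the cholesterol list, and without ccl5 replicate 3 it was -0.17 for the G2/M list, -0.32 for the MYC list and -0.12 for the cholesterol list. The G2/M list was not called without control replicate 3 (-0.17, adjusted p = 0.152). The ribosomal protein shift lay between -0.56 and -0.38 in the 6 fits that left out a library and was called in each, and the oxidative phosphorylation shift lay between -0.17 and -0.11. With primary transplant libraries only, the mean log2 fold change was smaller for ribosomal proteins (-0.20), the MYC list (-0.26) and oxidative phosphorylation (-0.05, adjusted p = 0.564, not called). With 1 surrogate variable the monocyte (mean log2 fold change 0.69, adjusted p = 0.206), oxidative phosphorylation (-0.15, adjusted p = 0.0995) and cholesterol (-0.29, adjusted p = 0.0995) calls ended, the last 2 at about the same size. The oxidative phosphorylation call also ended with DESeq2 size factors (-0.14, adjusted p = 0.0521) and without a filter on low counts (-0.13, adjusted p = 0.144). fry called 0 lists, with a smallest adjusted p of 0.448. Over the 16 alternatives run for each list, including fits to fewer libraries, adjusted p ranged from 3.16e-19 to 0.71 for ribosomal proteins, 4.34e-10 to 0.71 for the MYC list, 1.01e-16 to 0.871 for the G2/M list, 0.000232 to 0.71 for the monocyte list, 0.00219 to 0.71 for cholesterol synthesis and 0.0393 to 0.71 for oxidative phosphorylation. Ribosomal protein genes have many processed pseudogenes, so reads shared with copies leave single members of that list uncertain.

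**Figure D2:**
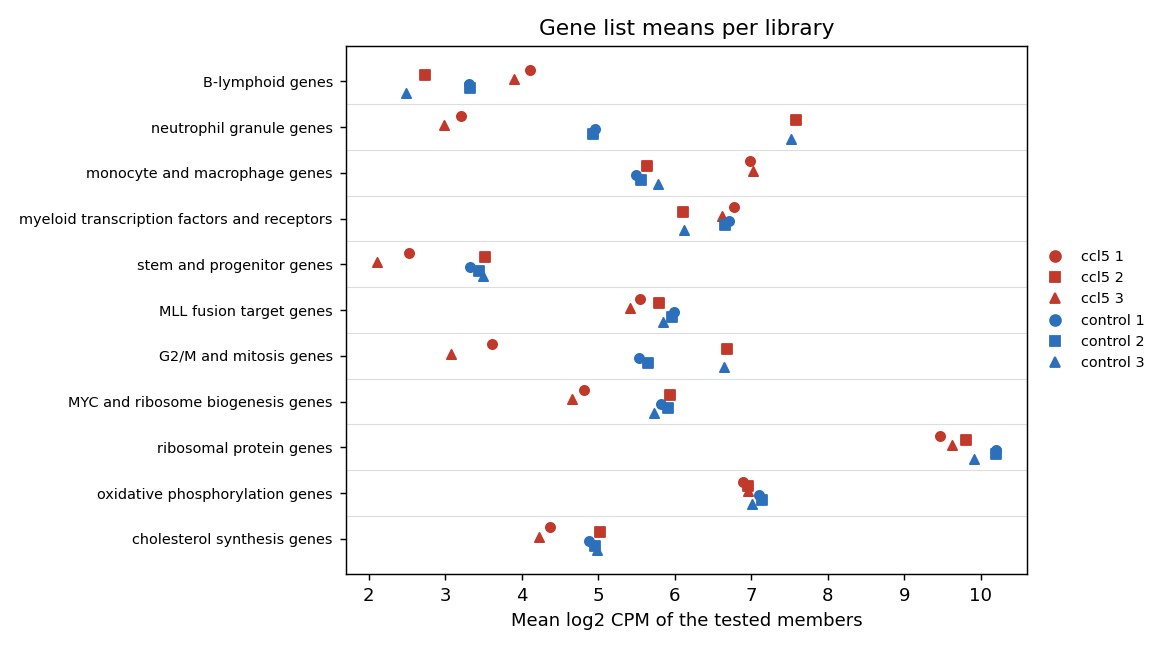
Mean log2 CPM of the tested members of 11 gene lists, with 1 point per library, coloured by group and shaped by replicate. In the G2/M list ccl5 replicates 1 and 3 lie at 3.61 and 3.08 and ccl5 replicate 2 at 6.68, beside control replicate 3 at 6.64.

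With all 6 libraries the other lineage lists did not shift. B-lymphoid genes were split evenly, 8 higher and 8 lower of 16 tested (camera adjusted p = 0.395), and the B-cell genes Pax5 and Ebf1 were at or near 0 in every library. Pax5 had at most 2 counts and Ebf1 at most 1. Of the list's members with the smallest p, Sox4 and Ptprcap are also expressed outside B cells. Cd22 measured 29.5, 3.73 and 24.0 CPM with CCL5 and 3.11, 2.77 and 2.64 CPM in controls, Sox4 measured 8.34 ± 4.54 against 2.53 ± 0.571 CPM, and Ptprcap measured 1.04 ± 0.211 against 2.01 ± 0.186 CPM. Il7r, the interleukin 7 receptor, measured 928, 53.9 and 1130 CPM against 191, 207 and 64.6 CPM (log2 fold change 2.19, SE 1.06, adjusted p = 0.40 in edgeR). Cd79a stayed under 1.1 CPM in all 6 libraries. With primary transplant libraries only, ccl5 replicates 2 and 3 against control replicate 3 alone, the B-lymphoid list had a mean log2 fold change of 1.25. Its mean log2 CPM was 2.73 and 3.90 in these ccl5 libraries and 2.48 in that control, so the shift lay mainly in ccl5 replicate 3.

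Neutrophil granule genes had a camera adjusted p of 0.197, myeloid transcription factors and receptors 0.571, and stem and progenitor genes 0.197. Among the fits that left out 1 library, camera at the preset correlation called the neutrophil list lower in some. These were the fits without ccl5 replicate 2 (mean log2 fold change -3.66, adjusted p = 0.00029), without control replicate 1 (-0.45, adjusted p = 0.029) and without control replicate 2 (-0.45, adjusted p = 0.0258). The list's mean log2 fold change was -0.62 with primary transplant libraries only, which leave a lone control. It was 0.94 with Y-linked libraries only, which leave a lone ccl5 library. Mpo, the myeloperoxidase gene, measured 4.99, 232 and 1.64 CPM with CCL5 and 6.15, 6.61 and 156 CPM in controls. Mmp8, a granule collagenase, measured 416 ± 148 against 122 ± 142 CPM, Csf3r, the G-CSF receptor, 219 ± 23.1 against 111 ± 77.8 CPM, and Padi4 95.4 ± 53.2 against 216 ± 58.9 CPM. Cebpa, a regulator of myeloid differentiation, measured 291 ± 38.4 against 142 ± 91.0 CPM (log2 fold change 1.03, SE 0.45) and Sfpi1, which encodes PU.1, 241 ± 43.3 against 178 ± 13.9 CPM (0.44, SE 0.19). Csf1r, the M-CSF receptor, measured 286 ± 177 against 98.5 ± 18.2 CPM, and Itgam, which encodes CD11b, 532 ± 74.0 against 653 ± 192 CPM. In ccl5 replicate 2 and control replicate 3, Cebpa measured 253 and 247 CPM, Sfpi1 196 and 193, and Csf1r 82.0 and 77.6. There Itgam measured 473 and 431 CPM, Mmp8 250 and 286, Csf3r 193 and 200, and Padi4 156 and 148. The group differences of these genes thus came mainly from the other libraries. Anpep measured 302, 11.8 and 249 CPM against 16.1, 18.3 and 9.79 CPM, and Egr1 measured 1.71, 0.489 and 1.37 CPM against 21.9, 24.6 and 0.495 CPM, so the groups overlapped for both. In the stem and progenitor list, Hmga2 measured 2.64, 1.10 and 2.46 CPM with CCL5 and 35.0, 36.0 and 1.32 CPM in controls. Cd27 had a log2 fold change of -0.61 (SE 0.27) and Gata2 measured 1.10 to 2.07 CPM against 0.495 to 7.74 CPM. Of 23 MLL fusion target genes, 7 were higher and 16 lower (camera adjusted p = 0.141). Meis1, the partner of Hoxa9, measured 36.3 ± 23.1 against 44.4 ± 16.3 CPM, and Pbx3 measured 65.0, 13.7 and 69.3 CPM against 7.48, 7.62 and 14.0 CPM.

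Of the remaining 13 tested lists none shifted. Camera adjusted p was 0.211 for NF-kB and inflammatory genes, where Tnf measured 2.85, 3.79 and 2.82 CPM with CCL5 and 61.8, 75.8 and 4.07 CPM in controls, and 0.194 for interferon response genes, where Ifi27l2a measured 7.12 ± 4.62 against 2.13 ± 0.453 CPM. It was 0.843 for immediate early and stress genes (Ier2, log2 fold change -1.35, SE 0.40), 0.876 for STAT5 and cytokine response genes (Socs3, 1.55, SE 0.47) and 0.141 for G1/S and DNA replication genes (Cdt1, 0.54, SE 0.14). It was 0.833 for glycolysis and hypoxia genes (Car9, -0.61, SE 0.19), 0.141 for unfolded protein and amino acid stress genes (Mthfd2, 39.4, 60.5 and 43.0 against 150, 174 and 59.0 CPM) and 0.482 for p53 target and apoptosis genes (Pmaip1, -1.72, SE 0.49). In ccl5 replicate 2 and control replicate 3, Ier2 measured 34.8 and 38.45 CPM, Socs3 17.4 and 17.3, and Pmaip1 77.7 and 88.9. There Cdt1 measured 53.4 and 41.7 CPM and Car9 21.9 and 25.0. The differences in Ier2, Socs3 and Pmaip1 thus lay mainly in the other libraries. Over the 25 tested lists, 0 members passed after adjustment over all genes and 0 when adjusted over the list alone.

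Lists for other cell types were low or did not shift. Of 26 T and NK cell genes 4 passed the filter and of 20 erythroid genes 2, too few to test; Bcl11b measured 2.71 ± 3.54 against 14.6 ± 8.58 CPM and Spnb1, which encodes erythroid spectrin, 0.478 ± 0.415 against 1.16 ± 0.343 CPM. Cd3e had 1 count in total and Hba-a1 had 0. Camera adjusted p was 0.865 for megakaryocyte, mast cell and basophil genes (Gp1ba, 1.71 ± 0.247 against 2.93 ± 0.535 CPM), 0.853 for stromal and endothelial genes (Pecam1, 48.4 ± 31.7 against 87.9 ± 6.05 CPM) and 0.29 for dendritic cell genes. In the dendritic list, the MHC class II gene H2-Eb1 measured 24.4, 0.794 and 25.6 CPM with CCL5 and 0.444, 0.480 and 0.770 CPM in controls. As signs of RNA quality, replication-dependent histone genes had a camera adjusted p of 0.963 (Hist1h1e, 2.17 ± 0.997 against 0.959 ± 0.199 CPM) and nuclear-retained noncoding RNAs 0.351. The file held none of the 13 mitochondrially encoded genes. Mean, median and test direction differed in sign for the megakaryocyte, STAT5, histone and nuclear-retained lists, none of which shifted.

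The libraries stood apart in a way that the treatment did not follow. Over the log2 CPM of all tested genes, ccl5 replicates 1 and 3 resembled each other (Pearson r across genes 0.993), as did control replicates 1 and 2 (0.995) and ccl5 replicate 2 and control replicate 3 (0.995). Every other pairing had r between 0.826 and 0.887; genes are not independent replicates. Differences within each of these pairs exceeded sampling noise (chi-square per gene 7.27, 4.48 and 3.55 for ccl5 replicates 1 and 3, ccl5 replicate 2 and control replicate 3, and control replicates 1 and 2), with a coefficient of variation of 7.3%, 5.13% and 4.62% in that order. No library was therefore an exact copy of another, and all 6 were kept. Separate preparations of 1 sample would also exceed sampling noise, so whether paired libraries are independent samples is open, and the p-values take no account of it. The pairs held 96.8% of the variance between libraries and the ccl5 and control groups 30.9%. The pairs were chosen from these same values, which raises their share. These shares also overlap and do not test the groups against the pairs.

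**Figure D3:**
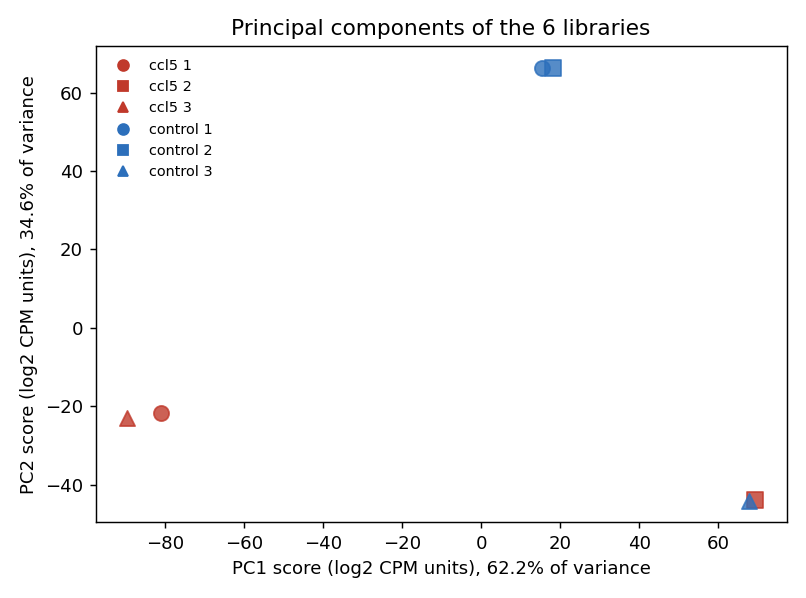
Scores of the 6 libraries on the first principal components of log2 CPM, which hold 62.2% (horizontal) and 34.6% (vertical) of the variance, with colour for the group and shape for the replicate. ccl5 replicate 2 and control replicate 3 lie together at 69.3 and 67.7 on the horizontal axis.

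Genes that mark each pair were chosen after their values were seen. In ccl5 replicates 1 and 3 Ftl1, ferritin light chain, took 70691 and 77881 CPM against 6122 to 16228 in the other libraries, Gpnmb 21798 and 20441 CPM against 1256 to 1655, and Psap 17253 and 15481 CPM against 1001 to 1083. ccl5 replicate 2 and control replicate 3 held primary and secondary granule genes, with Ngp at 4905 and 4714 CPM against 1.35 to 28.8 elsewhere, and Elane at 4548 and 4360 CPM against 12.8 to 226. They also had the highest level of the proliferation marker Mki67, 687 and 659 CPM against 61.8 to 201. Control replicates 1 and 2 held Slpi, the secretory leukocyte protease inhibitor, at 17947 and 18060 CPM against at most 1469, Ccnd1, cyclin D1, at 277 and 299 CPM against 1.43 to 9.12, and Stfa3 at 623 and 629 CPM against 0.570 to 1.77. Stfa3 and Ftl1 belong to families of near-identical copies or pseudogenes, so their counts are uncertain.

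Genes that differ between the sexes separated ccl5 replicates 1 and 3 from the other 4 libraries. Xist, the noncoding RNA of the inactive X chromosome, had 29408 and 25725 counts in ccl5 replicates 1 and 3, where the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0. In ccl5 replicate 2 and control replicates 1, 2 and 3 Xist had 40, 4, 3 and 77 counts and Ddx3y had 1640, 1969, 2537 and 2070. The groups are therefore unbalanced in this respect, with 1 of 3 ccl5 libraries and 3 of 3 control libraries holding Y-linked reads. In a fit added after the data were seen, with those 4 libraries (1 ccl5 against 3 control), 0 genes were called, the G2/M list had a mean log2 fold change of 0.64 (camera adjusted p = 2.01e-09), the MYC list 0.08, the cholesterol list 0.14 and the monocyte list -0.30, each opposite in sign to the fit with all 6. The ribosomal protein list kept its direction (-0.31, camera adjusted p = 5.87e-09). These p-values use the preset correlation; with an estimated correlation the adjusted p was 0.67 for the G2/M list and 0.731 for the ribosomal proteins. The lone ccl5 library was assumed to vary like the controls.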

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

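Of the alternatives here, only the fit to libraries with Y-linked reads was chosen after the result was seen. A fit with the 3 pairs of libraries as a term was also tried then; it is not counted among the alternatives, because the pairs were read from the same values. The other pairs lie wholly within a group, so its treatment estimate rests on ccl5 replicate 2 against control replicate 3 alone. Its calls are therefore not given. Mean log2 fold changes in that fit were -0.16 (monocyte), 0.04 (G2/M), 0.20 (MYC), 0.03 (cholesterol), -0.10 (ribosomal protein) and -0.04 (oxidative phosphorylation). The first 4 were opposite in sign to the fit with all 6 libraries. The count of 0 genes stayed at 0 with DESeq2 size factors, both filters, thinning, a 1.5-fold test, a threshold of 0.1, primary transplants only and Y-linked libraries only. It was 199 with DESeq2, 8097 with limma-voom and quality weights, and 1 with a surrogate variable; leaving out 1 library gave 0 to 3299. The count of 6 lists was 16 with primary transplants only, 0 with an estimated correlation and 0 with fry; leaving out 1 library gave 4 to 9. Leaving out receptor segments and haemoglobin moved nothing, as those 8 genes had no counts. Primary transplants only leaves a lone control, assumed to vary like the ccl5 libraries. Signs turned as follows; the cause was not tested, beyond fewer libraries. With the surrogate variable the myeloid factor list had a mean log2 fold change of -0.20, and with limma-voom Mpo had -0.93. With primary transplants only, log2 fold changes were 0.86 for Egr1, 0.40 for Hmga2, 1.33 for Gata2, 0.05 for Odc1, 0.55 for Ccr1, 1.05 for Cd79a, 0.17 for Itgam, -0.42 for Mpo and 0.25 for the stem cell list. With Y-linked libraries only they were -0.32 for Anpep, 0.11 for Bub3, 0.44 for Anln, 0.45 for Kif23, 0.069 for Cd79a, -1.52 for Il7r, -0.27 for Csf1r, 0.50 for Meis1, and for the lists -0.30 (monocyte), 0.64 (G2/M), 0.077 (MYC), 0.14 (cholesterol), -0.52 (B-lymphoid), 0.94 (neutrophil) and -0.55 (myeloid factors). Leaving out 1 library gave -3.66 to 1.59 for the neutrophil list, -4.07 to 3.66 for Mpo, -0.94 to 0.068 for Meis1 and -1.11 to 0.62 for the stem cell list. Depth ranged from 13421100 to 18445095 counts, and thinning to the smallest total changed no call.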

Other observations

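The tests on the closest library of ccl5 replicate 2, on sex-linked reads, on the name of ccl5 replicate 3 and on the genes read in ccl5 replicate 2 alone were chosen only after the result was seen. Since ccl5 replicate 2 and control replicate 3 were so alike, their small differences are given as values of 1 library against 1, without a p-value, and percentiles among random lists describe these 2 libraries and not the conditions. Of 10904 genes with an average log2 CPM of at least 1 over the 2 libraries, only Socs1, a feedback inhibitor of cytokine signalling, was at least 2-fold higher in ccl5 replicate 2 (log2 ratio 1.03, from 59 and 31 counts). Only 2810405K02Rik was at least 2-fold lower (-1.05, from 59 and 138 counts). MYC and ribosome biogenesis genes had a median log2 ratio of 0.21, with 25 of 30 higher in ccl5 replicate 2, and G1/S genes had 0.14, with 29 of 32 higher, each at the percentile of 100 among 10000 random lists. Ribosomal protein genes had -0.13, with 70 of 73 lower, and monocyte and macrophage genes -0.10, with 27 of 32 lower. Megakaryocyte, mast cell and basophil genes had -0.51, with 8 of 9 lower, at a percentile of 0.06.

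Libraries of the same treatment differed by similar amounts in some of these lists. Between ccl5 replicates 1 and 3 the median log2 ratio was 0.46 for G2/M genes, 0.37 for G1/S genes and -0.16 for ribosomal protein genes. Between control replicates 1 and 2 it was -0.10 for MYC and ribosome biogenesis genes and -0.10 for G1/S genes. The megakaryocyte, mast cell and basophil list had 0.09 and -0.05 in those 2 comparisons, both within the range of random lists. Its members with the most counts were Mcpt8, a basophil protease, with 127 counts in ccl5 replicate 2 and 212 in control replicate 3, and Pf4, platelet factor 4, with 86 and 137 counts.

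The 6 libraries split 3 against 3 in 10 ways, too few for a share under 0.05. The real grouping called 0 genes and the highest of the other splits 0; since no count can be lower than 0, this comparison says nothing. For lists the real grouping called 6 and the highest other split called 12, and 6 of the 10 splits gave as many or more. The splits that called 12 and 11 lists put control replicate 1 or 2 together with ccl5 replicates 1 and 3, which points to a structure of the samples.

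The first pattern is that the 6 libraries formed pairs that crossed the groups. Library depth is argued against, since after thinning to equal totals 6 of 6 libraries kept their closest library. A few abundant genes are argued against as well, since without the 100 most abundant genes 6 of 6 kept it. CCL5 treatment as the whole cause is argued against only by the pattern itself, and only if the labels are right. The highest r of ccl5 replicate 2 with another ccl5 library was 0.837, which restates the pattern and is not separate evidence. Different leukemias of origin may account for the pair of ccl5 replicates 1 and 3, which lacked Y-linked reads where the 4 other libraries had them. For the other pairs this cannot be told, since all 4 of their libraries had Y-linked reads. The labels give ccl5 replicates 2 and 3 the same name and control replicate 3 its stem, while ccl5 replicate 1 has another. They do not say what these names stand for. A wrong label on ccl5 replicate 3 may also be the cause of its place. Its r with ccl5 replicate 2, the only other library of its name, was 0.826. The same name may cover different leukemias, so this cannot be told apart. Exchanged labels elsewhere stay open and were not tested.

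The second pattern is a set of 12 genes read almost only in ccl5 replicate 2, by a criterion of at least 10 counts and over 8 times the CPM of every other library; the other 5 libraries had 0 such genes. They include Timd2 (103 counts), Bhmt (50), Dppa3 (45), Calcoco2 (43), Fbxo15 (38) and Dppa5a (30), several of them known from pluripotent cells. Pluripotent cells or their reads cannot be told from other sources. Of 24 pluripotent cell genes on a list 0 passed the same criterion, but most had few counts in any library, and ccl5 replicate 2 held the highest CPM for 10 of them where chance gives 4. Dppa2 had 12 counts there and at most 2 elsewhere, Zfp42 had 5 and 0, Pou5f1 had 5, Tdgf1 1 and Sox2 0. CCL5 treatment was not tested, since choosing genes read in ccl5 replicate 2 alone fixes what the other ccl5 libraries show. Activation of these genes in a part of the cells of that library may be the source and stays untested, as do reads carried over from a library of another kind.

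The third pattern is the 8097 genes called by limma-voom with quality weights where edgeR called 0. The weights themselves may be the cause: they were 0.068 for ccl5 replicate 2 and 0.125 for control replicate 3 and between 2.22 and 4.54 for the other libraries, and without weights limma-voom called 0 genes. The weights left mainly a comparison of ccl5 replicates 1 and 3 with control replicates 1 and 2, which is also what leaving out ccl5 replicate 2 approaches, with 3299 calls. No biological explanation was tested for this pattern.

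Xist traces differed among the libraries with Y-linked reads, with 40 counts in ccl5 replicate 2 and 77 in control replicate 3 against 4 and 3 in control replicates 1 and 2.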
